A study of Homo sapiens with 6 samples.

How the data were processed

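RNA of NCI-H226 cells was measured in 6 libraries, 3 from cells given the vehicle DMSO and 3 from cells given 500 nM of the compound HC278, all for 24 h. Per the labels' protocols, the cells grew in DMEM with 10% FBS, RNA was taken up in Trizol, and libraries were made with Illumina's stranded kit for mRNA. The labels write the compound's name in more than one way (HC278, HC31278A), and these were taken as 1 compound because every treated sample carries the same treatment text. Groups and replicate numbers came from the sample titles, which number the DMSO libraries 1, 2 and 3 and the HC278 libraries 1, 2 and 6.

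The deposited table holds 60676 genes with 4 measures per library. Per the file headers, the first measure is the raw count of reads per gene, in whole numbers. TPM values were computed by the authors per the file headers, and they sum to the same total in each library. RPKM values were also computed by the authors per the file headers, over a library total above the sum of the counts, which was recovered from the values and from exon lengths of GENCODE release 29. The counts fell short of that total by between 4.60% and 7.85% of it, and what the remainder holds is not stated. The last deposited measure, named CPM per the file headers, is a scaled coverage signal: its columns sum to between 871859 and 1091291, so the authors divided by an adjusted library size. Build hg38 is named in the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. Of the gene identifiers, 96.4% are in GENCODE release 29, and 79.1% of those have identical start, end and strand there, so coordinates are printed as the table gives them and that release served only for gene type, GC content and summed exon length. Tests used the counts alone. The TPM, RPKM and CPM columns were used to learn how the table was made.

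Total counts were 32617373, 33181814 and 32532357 in DMSO replicates 1, 2 and 3, and 31624893, 32646223 and 30486316 in HC278 replicates 1, 2 and 6. At this depth 3 counts correspond to 0.0904 to 0.0984 CPM, which covers counting error only. No pair of libraries in a group agreed within sampling noise: the chi-square per degree of freedom over genes with at least 20 counts in the pair was 4.02 for DMSO replicates 1 and 2, the lowest, and 313 for HC278 replicates 1 and 6, the highest.

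Counts were tested with edgeR 4.0.16 in R 4.3.3, by glmQLFit and glmQLFTest with TMM factors, after filterByExpr by group with its minimum count of 10, which left 15510 genes. The TMM factors ran from 0.903 in HC278 replicate 1 to 1.12 in HC278 replicate 6. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes are called changed. Standard errors of log2 fold changes are the fold change divided by the square root of F, and CPM values were computed over the TMM-scaled library size and are given as mean ± SD over 3 libraries. The common biological coefficient of variation was 26.0%. For 30 gene lists, camera of limma 3.58.1 was run on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. It was run again with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way, was run as well. The lists, the tests, the settings to vary and the rule for named genes were fixed before the data were examined. That rule names the 4 TEAD genes with YAP1 and WWTR1 in every library, and all tested members of the YAP/TEAD list. It adds the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, passing over symbols of clones, pseudogenes and locus numbers, and up to 4 members with the smallest adjusted p of every other list.

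On simulated counts with the measured spread of HC278 against DMSO (15265 genes), the test recovered 25% of 2-fold and 88% of 4-fold changes among 100 genes each, and called 9 unchanged genes. A simulated list of 20 genes moved by 1.5-fold gave a camera p of 5.18e-11, and 4 of 100 random lists had an unadjusted p under 0.05. Such random lists hold no shared variation, which real lists do.

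Settings fixed beforehand as variations were DESeq2 size factors within edgeR, upper quartile factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 10 counts in 3 libraries, glmTreat against a fold of 1.5, the replicate number as a block, and each library left out in turn. Added after the data were seen were a fit without DMSO replicate 3 and HC278 replicate 6, fits with a smooth trend (loess, span 0.5) of each library on gene model length or on GC content taken out, limma-voom with library weights, and camera with an estimated correlation without HC278 replicate 6 and without both libraries. All 15510 tested genes had a length and 99.1% a GC value. Figures were drawn with matplotlib. No sample or measurement column was left out. Of the genes that the rule names, 2 are not reported here.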

Results

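Expression was measured by RNA sequencing in NCI-H226, an established human cell line that the labels describe as mesothelioma from the pleura. Cells had been given DMSO or 500 nM HC278 for 24 h, with 3 libraries in each group. The series title calls HC278 a degrader of TEAD, and the comparison asks which transcripts changed under it. TEAD proteins are transcription factors that bind DNA and act with the co-activators YAP1 and WWTR1 (TAZ) at the end of the Hippo pathway. Depth was even, from 30486316 to 33181814 counts in genes per library. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Protein was not analysed here.

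TEAD4 transcripts were lower under HC278, at 31.5 ± 6.59 CPM (SD, n = 3) against 52.7 ± 4.46 CPM with DMSO, a log2 fold change of -0.74 (SE 0.18, edgeR quasi-likelihood test, adjusted p = 0.04999). TEAD4 (ENSG00000197905) lies on chromosome 12 at 2959330 to 3040676 on the plus strand of hg38. Its DMSO libraries were at 56.9, 53.1 and 48.0 CPM and its HC278 libraries at 38.0, 31.7 and 24.8 CPM. TEAD1 (ENSG00000187079, chromosome 11, 12674421 to 12944737, plus strand), the most abundant of the family, had 123, 133 and 180 CPM in DMSO replicates 1, 2 and 3. HC278 replicates 1 and 2 had 62.1 and 77.6 CPM of TEAD1, below all DMSO libraries, whereas HC278 replicate 6 had 213 CPM. With all 6 libraries the TEAD1 difference did not pass (log2 -0.31, SE 0.48, adjusted p = 0.746), and without HC278 replicate 6 it did (log2 -1.06, adjusted p = 0.00865). Without HC278 replicate 1 or 2 it was at -0.01 and -0.09, and with the length trend taken out at -0.41 (adjusted p = 0.428), none of which passed. Every setting in which TEAD1 passed left out HC278 replicate 6 or gave it little or no bearing. YAP1 followed the same arrangement, with 99.7, 102 and 132 CPM in the DMSO libraries and 64.4, 83.4 and 160 CPM in the HC278 libraries, and did not pass (log2 -0.11, adjusted p = 0.880). WWTR1 had 14.2, 16.0 and 23.9 CPM in the HC278 libraries against 10.3, 10.5 and 12.2 CPM with DMSO, and did not pass (log2 0.71, adjusted p = 0.0969). TEAD2 had 4.03 ± 0.282 against 2.83 ± 0.358 CPM (adjusted p = 0.113) and TEAD3 39.8 ± 1.43 against 33.7 ± 1.54 CPM (adjusted p = 0.196), and neither passed. Without HC278 replicate 6, YAP1 passed as lower (log2 -0.59, adjusted p = 0.0337), and TEAD2 (log2 0.57, adjusted p = 0.0342) and WWTR1 (log2 0.45, adjusted p = 0.0298) as higher, while TEAD3 did not pass (log2 0.26, adjusted p = 0.0577). YAP1 was at 0.13, 0.01 and 0.02 without HC278 replicate 1, HC278 replicate 2 or DMSO replicate 3, and did not pass. WWTR1 also passed as higher with the length trend (log2 0.70, adjusted p = 0.00871) or the GC trend (log2 0.80, adjusted p = 0.0142) taken out. It did not pass under any other scaling or filter. With library weights TEAD3 passed as higher (log2 0.32, adjusted p = 0.00201). The TEAD4 call stood at the threshold: over 18 other settings its log2 fold change lay between -0.97 and -0.60, and it passed in 10, among them DESeq2 (adjusted p = 0.00380) and the length trend taken out (0.00327), and not in 8. Those 8 were DESeq2 size factors (0.0527), upper quartile factors (0.0694), no filter (0.0511), glmTreat against a fold of 1.5 (0.615), and the fits without DMSO replicate 1, 2 or 3 (0.180, 0.184 and 0.137) or HC278 replicate 2 (0.170).

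**Figure D1:**
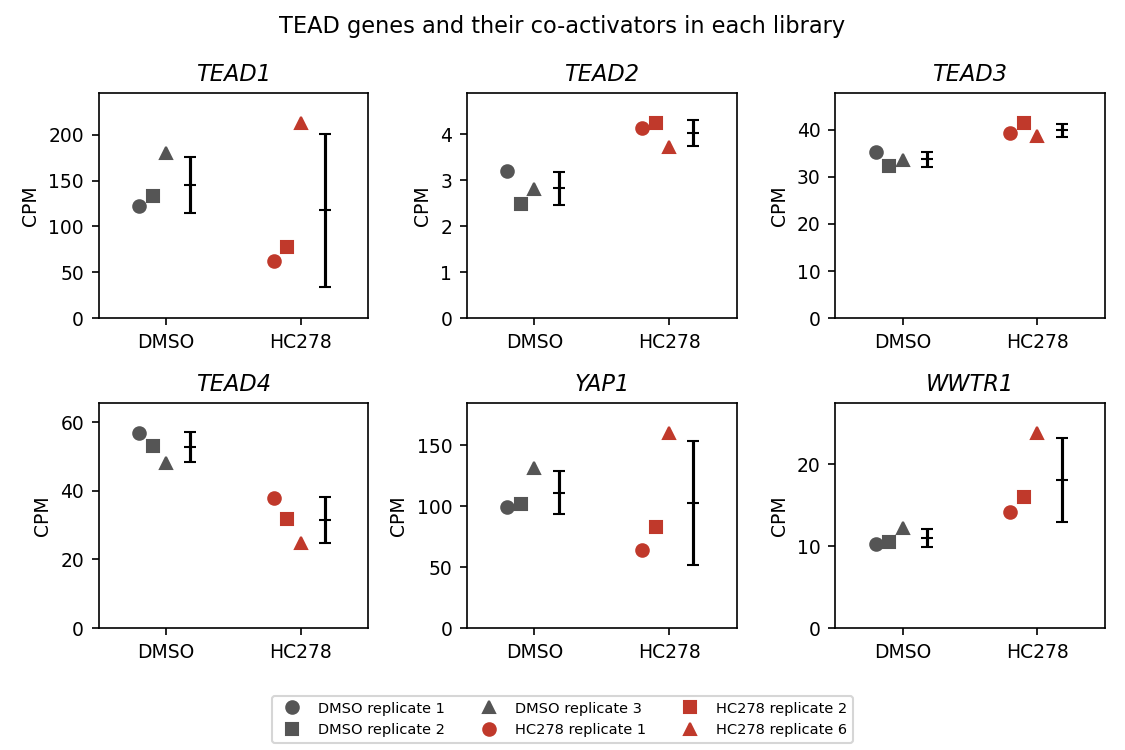
CPM (y axis) of the TEAD genes, YAP1 and WWTR1 in each of the 6 libraries, with DMSO in grey and HC278 in red, and the mean and SD of 3 libraries beside the points. TEAD1 and YAP1 are lowest in HC278 replicates 1 and 2 and highest in HC278 replicate 6 (213 and 160 CPM).

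Several known targets of YAP and TEAD fell under HC278. Of 22 members of the fixed list, 8 passed and were lower, 0 passed as higher, 14 did not pass, and 13 were lower when adjusted over the list alone. F3, which encodes tissue factor and starts blood clotting, fell from 97.5 ± 5.86 to 14.4 ± 3.61 CPM (SD, n = 3; log2 -2.75, SE 0.20, adjusted p = 0.00393). ANKRD1, a standard reporter of YAP activity, fell from 312 ± 10.6 to 78.2 ± 7.02 CPM (log2 -1.996, SE 0.12, adjusted p = 0.00393). CCN2, encoding connective tissue growth factor, fell by 1.44 on the log2 scale (SE 0.26), from 54.9 ± 0.674 to 20.3 ± 7.09 CPM. IGFBP3, a binding protein of insulin-like growth factors, fell by 1.44 (SE 0.23), and CCDC80 by 1.17 (SE 0.14). Smaller falls were those of NUAK2 (log2 -0.64), of the receptor tyrosine kinase AXL (log2 -0.60) and of GADD45A (log2 -0.58). CCN1 did not pass, at 493 ± 89.0 against 780 ± 39.3 CPM (log2 -0.66, adjusted p = 0.0589), nor did TGFB2 (log2 -1.80, SE 0.52, adjusted p = 0.0831), LATS2, AMOTL2, FOXF2 or NT5E, which had log2 values from -0.81 to -0.49. CRIM1, ASAP1, ARHGEF17, FJX1, RBMS3, MYOF, PTPN14 and DOCK5 had log2 values between -0.36 and 0.17. F3 lies on chromosome 1 at 94529173 to 94541759, ANKRD1 on chromosome 10 at 90912096 to 90921276 and CCN2 on chromosome 6 at 131948176 to 131951372, each on the minus strand. The list had a median log2 fold change of -0.59 and a camera adjusted p of 5.07e-07, which became an adjusted p = 0.466 with an estimated correlation. Without DMSO replicate 3 and HC278 replicate 6, which stood apart from the others along gene length, 17 members were lower and 0 higher. With all 6 libraries and the length trend taken out, 11 were lower and 0 higher.

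**Figure D2:**
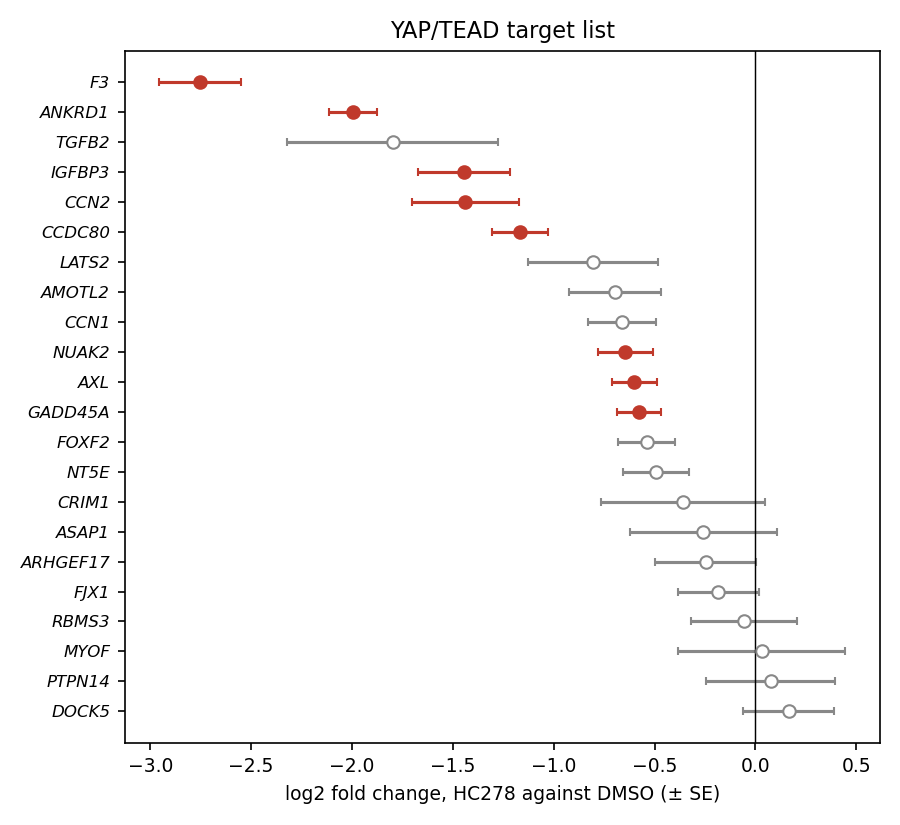
Log2 fold change of HC278 against DMSO (x axis) with its SE for the 22 members of the YAP/TEAD target list; filled red points passed an adjusted p of 0.05 and open grey points did not. All 8 that passed lie below 0, from F3 at -2.75 to GADD45A at -0.58.

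Over all genes, 1672 of 15510 tested changed under HC278, 837 higher and 835 lower. Of these, 911 changed by at least 1 on the log2 scale, 521 upwards and 390 downwards. NPPB, which encodes the precursor of B-type natriuretic peptide, fell furthest among named genes, from 182 ± 38.6 to 6.13 ± 2.08 CPM (log2 -4.90, SE 0.34, adjusted p = 0.00393; ENSG00000120937, chromosome 1, 11857464 to 11858945, minus strand). KRT34, a hair keratin, fell from 264 ± 24.96 to 20.1 ± 6.74 CPM (log2 -3.71, SE 0.30), and the hair keratin-associated gene KRTAP2-3 by 3.96. Other large falls were those of GPR1 (log2 -3.94), the regulator of G protein signalling RGS7 (log2 -3.57), the nucleoside transporter SLC28A3 (log2 -3.53), FRMPD3 (log2 -3.30), the formin FMN2 (log2 -3.04), the activin subunit INHBB (log2 -2.84) and KCTD4 (log2 -2.76). Among called genes with a mean of at least 1 CPM that the rule for named genes kept, the largest rise was that of CRISPLD2, from 1.32 ± 0.238 to 16.2 ± 5.04 CPM (log2 3.61, SE 0.29, adjusted p = 0.00393, ENSG00000103196, chromosome 16, 84819985 to 84920768, plus strand). PTGES, the inducible synthase of prostaglandin E, rose from 1.33 ± 0.128 to 13.5 ± 0.401 CPM (log2 3.34, SE 0.15), and the matrix metalloproteinase MMP9 from 0.365 ± 0.110 to 4.41 ± 0.0690 CPM (log2 3.58, SE 0.25). PDE7B (log2 3.51), PAK6 (log2 3.33), CAMK2A (log2 2.88), the transcription factor NFE2 (log2 2.88), the pro-apoptotic BMF (log2 2.85) and KLHL4 (log2 2.79) were also among the 10 largest rises kept by the rule for named genes. PAK6, PDE7B and KCTD4 are uncertain, because BUB1B on the same strand, AL138828.1 on the opposite strand and GTF2F2 on the opposite strand overlap them with counts equal to 822%, 82.4% and 2173% of theirs. BUB1B is 1 of the 31 mitosis genes below, all with log2 values of -0.59 or lower. That argues against its reads as the source of the rise of PAK6, whose size stays uncertain. All 1672 changed genes had no overlap between the groups' libraries, as did 34.6% of tested genes against 10% expected by chance. The count depended on single libraries: it was 164, 0 and 246 without DMSO replicate 1, 2 or 3 and 819, 252 and 6413 without HC278 replicate 1, 2 or 6, and with 0 calls 2864 genes still had an unadjusted p under 0.05 in edgeR, the only tool run on those subsets. All 1672 kept their sign in every one of these fits, which their lack of overlap between groups all but fixed in advance. No gene named here passed without DMSO replicate 2.

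**Figure D3:**
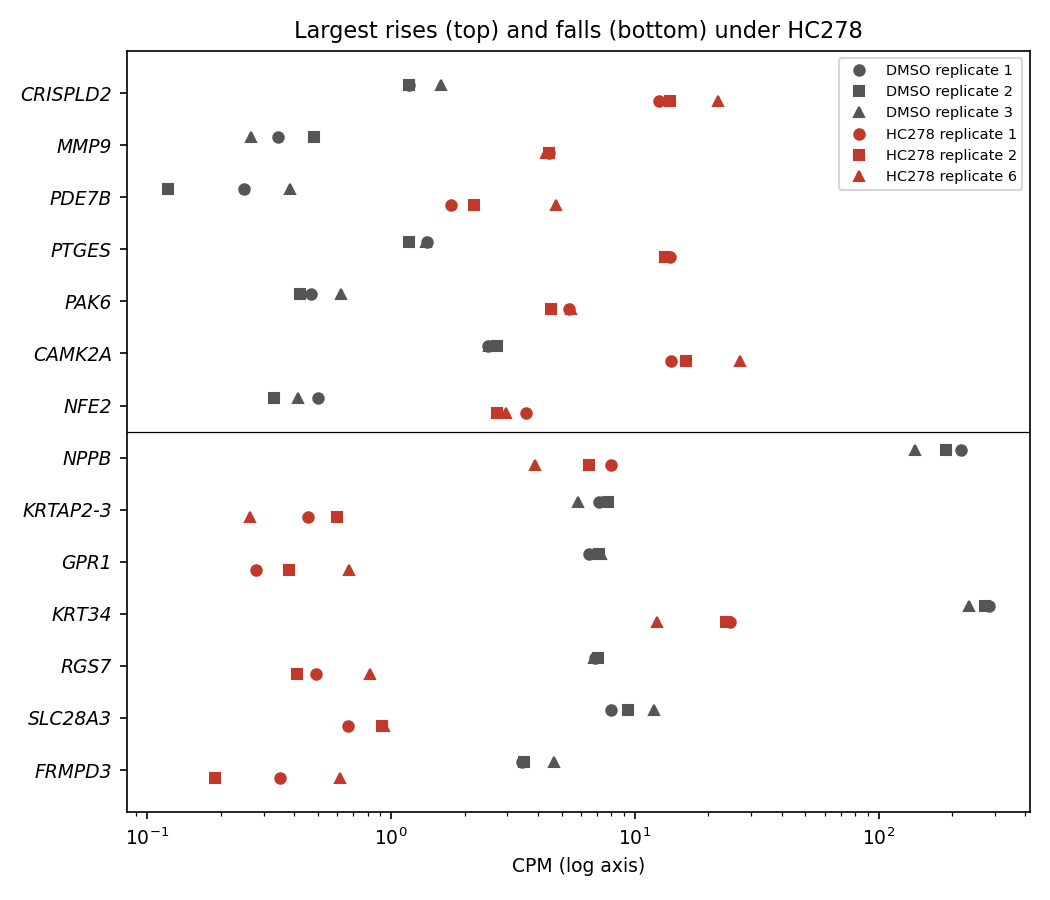
CPM on a log axis (x axis) in each library for the 7 largest rises (upper part) and 7 largest falls (lower part) among called genes with a mean of at least 1 CPM that the rule for named genes kept, with DMSO in grey and HC278 in red. The groups do not overlap for any of these genes; the mean of NPPB went from 182 to 6.13 CPM and that of CRISPLD2 from 1.32 to 16.2 CPM.

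Many genes of cell division were lower under HC278. Of 35 genes of DNA replication, 29 fell and 0 rose, and 34 fell when adjusted over the list alone. They included CDC6, which loads the replicative helicase, from 88.1 ± 3.13 to 23.2 ± 4.70 CPM (log2 -1.93, SE 0.17, adjusted p = 0.00475), and CDK2, the kinase of the entry into S phase, from 31.0 ± 2.25 to 10.5 ± 0.719 CPM (log2 -1.56, SE 0.12). UHRF1 fell by 1.86 and RFC3, a subunit of the clamp loader, by 1.79 on the log2 scale. Of 31 genes of mitosis, 17 fell and 0 rose, and all 31 fell when adjusted over the list alone. CDK1, the kinase that drives mitosis, went from 94.4 ± 3.47 to 38.0 ± 2.48 CPM (log2 -1.31, SE 0.11, adjusted p = 0.00393), CCNA2, which EXOSC9 overlaps on the opposite strand with 58.9% of its counts, fell by 1.29, and AURKA fell by 1.13. NEK2, a kinase of centrosome separation, fell by 1.01. CCND1 (cyclin D1), the only one of 13 genes of MAPK output to pass (camera adjusted p = 0.246 for that list), fell from 296 ± 24.8 to 150 ± 3.62 CPM (log2 -0.98), and MYC fell from 122 ± 2.81 to 69.1 ± 6.49 CPM (log2 -0.82). Among 20 CDK inhibitors and quiescence genes, CDKN1C (log2 1.72), FOXO4 (log2 0.96) and KLF2 (log2 0.63) rose and 0 fell (camera adjusted p = 0.113), while CDKN1A was at 0.16 (adjusted p = 0.560). Without HC278 replicate 6, 5 of these genes rose and 3 fell, and of the MAPK output genes 3 rose and 5 fell. The median log2 fold change was -1.19 for DNA replication and -0.93 for mitosis, with camera adjusted p of 2.05e-22 and 2.4e-16. With an estimated correlation these became adjusted p = 0.466 and adjusted p = 0.236. Without DMSO replicate 3 and HC278 replicate 6, all 35 and all 31 were lower. With all 6 libraries and the length trend taken out, 33 and 27 were.

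A further 4 lists passed camera, and none of them did so with an estimated correlation. Among 17 genes of the integrated stress response, 5 fell and 2 rose (camera adjusted p = 0.00197 downwards, adjusted p = 0.481 with an estimated correlation). The amino acid transporter SLC7A5 fell from 517 ± 9.35 to 225.7 ± 13.4 CPM (log2 -1.20), PSAT1 of serine synthesis from 230 ± 3.78 to 81.2 ± 13.6 CPM (log2 -1.50), and STC2 by 1.18. VLDLR and CHAC1 fell too, and DDIT4, an inhibitor of mTORC1, rose (log2 1.48), as did CEBPB. Without HC278 replicate 6, 11 genes of this list fell and 3 rose, and its median went from -0.71 to -0.45; of the growth factors and receptors below, 9 then fell and 1 rose. Of 20 growth factors and receptors, 3 fell and 1 rose (camera adjusted p = 0.0154 downwards, adjusted p = 0.466 with an estimated correlation). FGF1 fell from 1.80 ± 0.190 to 0.195 ± 0.0743 CPM (log2 -3.20, SE 0.31), ERBB3 from 22.5 ± 1.25 to 7.48 ± 1.14 CPM (log2 -1.59) and NRG1, a ligand of ERBB3, from 52.7 ± 2.35 to 26.3 ± 1.59 CPM, whereas PDGFB rose from 2.78 ± 0.376 to 10.6 ± 0.645 CPM (log2 1.93). This list, with a median of -0.25, did not pass without HC278 replicate 1 (median -0.15, adjusted p = 0.109) or with the length trend taken out (median -0.30, adjusted p = 0.0510). Of 16 NRF2 targets, 5 rose and 0 fell (camera adjusted p = 0.0154 upwards, adjusted p = 0.481 with an estimated correlation). They included the aldo-keto reductases AKR1B10 (log2 2.02), AKR1C3 (log2 1.61), AKR1C1 (log2 1.35) and AKR1C2 (log2 1.23), the AKR1C genes being near-identical copies whose counts may be shared. NQO1 and HMOX1 did not pass, at 0.55 and 0.71. Without DMSO replicate 3 and HC278 replicate 6, 11 NRF2 targets were higher and 3 lower. With all 6 libraries and the length trend taken out, 7 were higher and 0 lower.

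Interferon-stimulated genes had a camera adjusted p of 0.00197 upwards, but an adjusted p = 0.652 with an estimated correlation and an adjusted p = 0.109 with fry. Of 19 tested, 3 rose and 0 fell, and 4 rose when adjusted over the list alone. IRF9, part of the complex that carries type I interferon signals, rose from 25.5 ± 2.57 to 51.4 ± 2.51 CPM (log2 1.01, SE 0.12, adjusted p = 0.00771). IFI27 rose from 4.76 ± 1.36 to 11.4 ± 2.28 CPM (log2 1.26) and IFIT1 from 20.4 ± 1.73 to 36.2 ± 7.55 CPM (log2 0.83), the latter uncertain because LIPA overlaps it on the opposite strand with 967% of its counts. Several other members were raised in HC278 replicate 6 alone: RSAD2 had 1.54, 1.08 and 6.66 CPM in HC278 replicates 1, 2 and 6, against 1.13, 1.39 and 0.975 CPM with DMSO. The list's median log2 fold change was 0.91 and fell to 0.36 without HC278 replicate 6, where the list did not pass (adjusted p = 0.103).

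**Figure D4:**
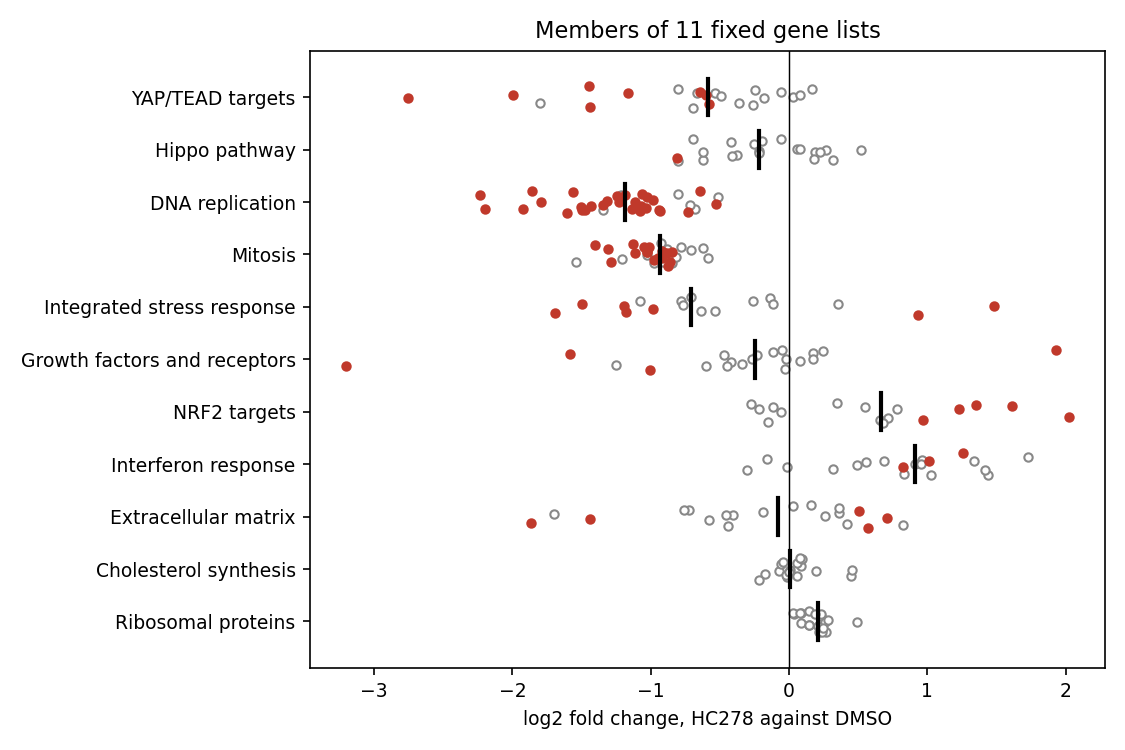
Log2 fold change of HC278 against DMSO (x axis) for each tested member of 11 of the 30 fixed lists, with a black bar at the list's median. Filled red points passed an adjusted p of 0.05: all 29 in DNA replication and all 17 in mitosis lie below 0, and 0 ribosomal protein genes passed.

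Markers of cell identity moved in both directions. Among 13 mesothelial and epithelial markers 3 rose and 1 fell: calretinin (CALB2) rose from 11.4 ± 1.66 to 29.1 ± 9.76 CPM (log2 1.35), ITLN1 and UPK3B rose by 1.36 and 1.05, and UPK1B fell from 11.8 ± 0.123 to 3.41 ± 0.971 CPM (log2 -1.79). None of 9 mesenchymal markers passed, nor either of 2 tested fibroblast markers. Of 4 tested immune and endothelial markers CD68 rose from 37.5 ± 0.506 to 70.3 ± 7.98 CPM (log2 0.91) and CD14 from 0.678 ± 0.121 to 1.71 ± 0.396 CPM (log2 1.33), while PTPRC, CD3E and PECAM1 were too low to be tested. The 1 tested squamous or lung marker, NAPSA, had 0.0907 ± 0.0292 and 0.383 ± 0.111 CPM and is overlapped on the opposite strand by NR1H2 with far more counts.

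In 20 extracellular matrix genes 3 rose and 2 fell. LOX, which cross-links collagen, fell from 285 ± 15.8 to 78.3 ± 12.0 CPM (log2 -1.86, SE 0.15) and COL8A1 by 1.44, whereas COL6A1 (log2 0.57), COL6A2 (log2 0.50) and BGN (log2 0.71) rose. Of 21 actin and SRF genes, the contractile genes CNN1 (log2 -1.76) and TPM1 (log2 -1.10) fell and the integrin ITGA5 (log2 0.63) rose. Both tested CYP1 genes rose among 4 AHR targets, CYP1B1 by 2.49 and CYP1A1 by 0.77 on the log2 scale. CA9 rose (log2 1.76), and HK2 (log2 -0.97) and ADM (log2 -0.86) fell, among 18 hypoxia and glycolysis genes, CA9 being uncertain because ARHGEF39 overlaps it on the opposite strand with 138% of its counts. JUNB rose (log2 1.11) and MYC fell among 13 AP-1 and immediate early genes. TNFAIP2 (log2 1.01) and NFKBIA (log2 0.61) rose among 17 NF-kB and cytokine genes. BMF alone rose among 9 pro-apoptotic BCL2 relatives, RASSF1 alone fell (log2 -0.81) among 21 Hippo pathway genes, XBP1 alone fell (log2 -0.76) among 13 ER chaperone genes, and TEAD4 alone passed among 9 TEAD factors and co-factors. No member passed among 22 p53 targets, 17 genes of cholesterol synthesis, 12 TGF-beta and BMP targets, 8 survival factors, 13 mitochondrial transcripts or 19 ribosomal protein genes. With all 6 libraries and no setting varied, none of the lists in this paragraph or among the identity markers passed camera, and the adjusted p closest to the threshold was 0.0541, for the immune and endothelial markers. These counts and calls depended on the libraries. Without HC278 replicate 6, where 6413 genes were called, 6 p53 targets rose and 7 fell, as did 2 and 8 genes of cholesterol synthesis, 2 and 3 TGF-beta and BMP targets, and 2 and 3 mesenchymal markers. In the same fit 8 ribosomal protein genes rose and 0 fell, and 12 Hippo pathway genes fell and 0 rose. Camera with the preset correlation then passed for the Hippo pathway (median -0.49, adjusted p = 0.000993), the ribosomal protein genes (median 0.50, adjusted p = 0.00174) and the extracellular matrix (median -0.44, adjusted p = 0.0263). The Hippo and ribosomal lists also passed without DMSO replicate 3 and HC278 replicate 6 (adjusted p = 0.00287 for each). With all 6 libraries and the length trend taken out, 0 ribosomal protein genes passed (median 0.11). In that fit 5 Hippo pathway genes fell and 0 rose (median -0.21, camera adjusted p = 0.102). The length trend was not taken out of the fits with libraries left out, so a part of gene length in their calls stays open. With an estimated correlation the Hippo, ribosomal and extracellular matrix lists did not pass. They had an adjusted p = 0.646 without HC278 replicate 6, and the Hippo and ribosomal lists an adjusted p = 0.744 without both libraries. Nor did DNA replication and mitosis pass that form of camera (adjusted p = 0.504 for each without HC278 replicate 6, 0.631 without both libraries). Failing it therefore says little about any 1 list. With the preset correlation ER chaperones passed camera in 6 other fits, with an adjusted p from 0.0109 with no filter to 0.0481 with the length trend taken out. Immune and endothelial markers passed in 6, from 0.00768 without DMSO replicate 2 to 0.0426 with the length trend taken out, and squamous and lung markers with no filter (adjusted p = 0.000203). With an estimated correlation and all 6 libraries these 3 lists had an adjusted p of 0.560, 0.466 and 0.481. With fry they and the AHR and actin lists passed. The median and the camera direction had opposite signs for the p53, actin and hypoxia lists, and the TEAD factor list had a median of 0.24 and a mean of -0.03.

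HC278 replicate 6 and DMSO replicate 3 differed from the other libraries of their groups along gene length. Genes with a summed exon length over 8000 nucleotides had a median log2 difference of 0.58 in HC278 replicate 6 against HC278 replicates 1 and 2, and genes of up to 1000 nucleotides one of -0.92. The same values in DMSO replicate 3 against DMSO replicates 1 and 2 were 0.22 and -0.39. The library total behind the RPKM values exceeded the sum of counts by 7.85% of that total in HC278 replicate 6, against 4.60% to 5.49% in the other 5 libraries, and what the excess holds is not stated. Without both libraries 6322 of 15637 genes were called, 3048 higher and 3274 lower, 1663 of the 1672 among them. In that fit the groups still differed along the first principal component of log2 CPM over all 6 libraries. HC278 replicates 1 and 2 were there at -70.4 and -40.0, and DMSO replicates 1 and 2 at 5.59 and 13.8. Variation between libraries and the compound cannot be told apart in it. With a length trend taken out of every library 2691 were called, 1264 higher and 1427 lower, 1565 of the 1672 among them.

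**Figure D5:**
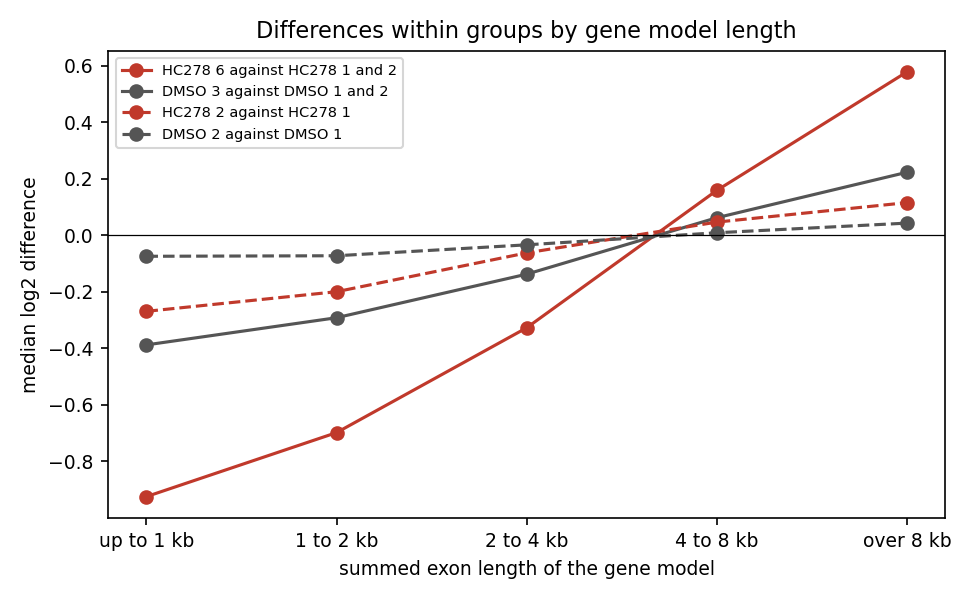
Median log2 difference between libraries of 1 group (y axis) in 5 classes of summed exon length (x axis), with HC278 in red and DMSO in grey. The solid lines compare HC278 replicate 6 and DMSO replicate 3 with the other 2 libraries of their groups and end at 0.58 and 0.22 for genes over 8000 nucleotides; dashed lines compare replicate 2 with replicate 1.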

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

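Fits without DMSO replicate 3 and HC278 replicate 6, with a length or GC trend taken out, and with library weights, and camera with an estimated correlation in fits without those libraries, were chosen after the data were seen. Within 1.5 times of the 1672 called genes lay the counts with DESeq2 size factors (1668), upper quartile factors (1682), library size alone (1359), limma-voom (1696), no filter (1215), the stricter filter (1668) and the GC trend taken out (2004). Other counts of changed, higher and lower genes were 2616, 1182 and 1434 with DESeq2; 343, 162 and 181 with glmTreat against a fold of 1.5; 6322, 3048 and 3274 without both length-skewed libraries; 2691, 1264 and 1427 with the length trend taken out; and 9196, 4583 and 4613 with library weights, where HC278 replicate 6 had a weight of 0.077. With no filter 553 genes were higher, as 32091 genes were tested. Leaving out 1 library gave 0 to 6413 changed, 0 to 3133 higher and 0 to 3280 lower genes, and the smallest adjusted p without DMSO replicate 2 was 0.0502. The cause of these shifts was not tested, apart from the fewer libraries or larger number of genes. All 1672 kept their sign in each of these fits, which is little of a check for genes chosen from these libraries without overlap between groups. The share of higher calls was 50.1%. Over the other fits with any calls it ran from 39.0% without DMSO replicate 1 to 60.0% with upper quartile factors, and it was 41.9% with the GC trend taken out.

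Replicate numbers 1 and 2 occur in both groups, and nothing says what they mark. The deviations from the group means correlated at 0.517 for number 1 and 0.183 for number 2. They also correlated at 0.384 and 0.327 for DMSO replicate 1 with HC278 replicate 2 and DMSO replicate 2 with HC278 replicate 1. For DMSO replicate 3 with HC278 replicate 6 the value was 0.685. Deviations cancel out within a group and the libraries that stand apart weigh most in them, so these values cannot tell whether the numbers mark pairs. With the replicate block, 8172 genes changed, 3954 higher and 4218 lower. TEAD1 (log2 -0.88, adjusted p = 5.32e-06), TEAD4 (log2 -0.66, adjusted p = 4.48e-05) and YAP1 (log2 -0.46, adjusted p = 0.00115) passed there as lower. TEAD2 (log2 0.57, adjusted p = 0.0181), TEAD3 (log2 0.26, adjusted p = 0.0207) and WWTR1 (log2 0.54, adjusted p = 0.00133) passed as higher. The Hippo pathway list passed camera with the preset correlation (median -0.37, adjusted p = 0.00329). In that fit DMSO replicate 3 and HC278 replicate 6, whose numbers have no partner, do not bear on the difference. The block fit therefore rests on replicates 1 and 2 of each group and leaves 1 residual degree of freedom. Its small p-values lean on variance pooled over genes and on numbers that are not known to mark pairs. There MYOF was at -0.37, PTPN14 at -0.29 and TIPARP at -0.23, each with the opposite sign to the fit without the block (0.03, 0.08 and 0.01), and PTPN14 was at -0.26 with library weights. Without those 2 libraries and without the block, MYOF, PTPN14 and TIPARP were at -0.35, -0.29 and -0.23, so the change of sign follows from the libraries that each fit leaves without bearing or, for HC278 replicate 6 in the weighted fit, with little weight.

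The YAP/TEAD list kept its direction and its camera call under each scaling, filter, correction and left-out library, with medians from -0.70 to -0.52, and with fry (adjusted p = 0.0163). With an estimated correlation the median of -0.59 had an adjusted p = 0.466. The median of -0.64 without HC278 replicate 6 had an adjusted p = 0.504, and that of -0.62 without both libraries an adjusted p = 0.631. That form of camera differs from the preset one in more than the correlation, so these losses cannot be put down to correlation alone. It takes its degrees of freedom from the few libraries, and with all 6 libraries none of the 30 lists passed it. The squamous and lung list, with 1 tested gene and so no correlation, went from an unadjusted camera p of 0.0457 to 0.116. Over the other settings the adjusted p of the YAP/TEAD list lay between 1.37e-10 and 0.0163. At this depth and spread 2-fold changes were recovered in 25% of simulated genes, so a gene that did not pass is not shown to be unaltered.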

Other observations

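Genes in this and the next paragraph were chosen after their values were seen. Several enzymes that make nucleotide precursors were lower under HC278. PRPS1, which makes the ribose donor of nucleotides, went from 324 ± 6.19 to 94.3 ± 4.18 CPM (SD, n = 3; log2 -1.78, SE 0.10, edgeR adjusted p = 0.00393), MTHFD2 of mitochondrial one-carbon metabolism from 212 ± 2.90 to 74.7 ± 5.30 CPM (log2 -1.51) and CTPS1 from 112 ± 4.13 to 56.0 ± 2.90 CPM (log2 -1.01). Other genes that fell were INHBA from 89.7 ± 16.2 to 23.1 ± 10.5 CPM (log2 -1.96), follistatin (FST) from 5.71 ± 0.345 to 0.898 ± 0.324 CPM (log2 -2.67) and FSTL1 from 569 ± 52.7 to 192 ± 57.4 CPM (log2 -1.57). A further hair keratin, KRT33B, fell from 8.01 ± 1.14 to 1.35 ± 0.731 CPM (log2 -2.58).

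Among the rises were complement genes, with CFB from 18.9 ± 1.29 to 51.7 ± 2.98 CPM (log2 1.45), C3 at 1.53, C1R at 1.05 and C1S at 0.97, and junction genes, with plakoglobin (JUP) from 3.95 ± 0.0231 to 13.3 ± 0.661 CPM (log2 1.75) and TJP3 at 2.22. The ubiquitin ligase FBXO32 (log2 1.44), PIK3IP1 (log2 2.02), DEPP1 (log2 1.92) and KLF9 (log2 1.48), all described as FOXO targets, rose too. The growth factor CSF1 rose from 67.1 ± 0.985 to 205 ± 16.2 CPM (log2 1.61), and the metalloproteinase MMP2 from 1.37 ± 0.244 to 8.78 ± 0.923 CPM (log2 2.68).

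Of the tests that follow, those on length and on DMSO replicate 3 in the first pattern, all those on the second pattern, those without HC278 replicate 6 and on length as the whole cause in the third, and the count of genes over the splits were chosen after the result was seen. Each of 4 hypotheses from the genes above was tested on members of the group that had not been used to notice it. For a fall of purine and pyrimidine synthesis as a group, 21 other enzymes had a median log2 fold change of -0.37, with 4 lower (PAICS, GMPS, PRPS2 and UMPS) and 0 higher, and a camera p of 0.0001003. Adjusted over the 4 hypotheses this was 0.000401 with the preset correlation, and it did not pass with an estimated correlation (adjusted p = 0.0521). Without DMSO replicate 3 and HC278 replicate 6 the median was -0.29. The hypothesis that nucleotide synthesis fell together with the genes of DNA replication may be worth following, and whether one came before the other was not tested. The other hypotheses were negative: 16 further FOXO targets had a median of 0.18 (a camera p of 0.421), 11 further complement genes one of 0.31 (a camera p of 0.157, with CD55 lower), and 22 further junction genes one of -0.11 (a camera p of 0.252), of which PKP3, LAMB3 and COL17A1 rose while CLDN1, OCLN, CGN and ESRP2 fell.

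HC278 replicate 6 and DMSO replicate 3 stood apart from the other libraries of their groups, and the first principal component, 51.7% of the variance of log2 CPM, had them at 42.7 and 48.3, HC278 replicates 1 and 2 at -70.4 and -40.0, and DMSO replicates 1 and 2 at 5.59 and 13.8. The second component, 35.5%, parted the groups. It had DMSO replicates 1, 2 and 3 at -37, -32.3 and -20.5 and HC278 replicates 1, 2 and 6 at 8.07, 15.4 and 66.2. HC278 replicate 6 lay furthest from DMSO there, so a stronger response as part of the source stays open. Over genes with a mean of at least 10 CPM, a trend on gene model length took up 35.9% (95% interval over genes 32.8 to 38.9) and a trend on GC content 17.0% (15.1 to 18.4) of the variance of HC278 replicate 6's deviation. Neither reached the 50% that had been set for a main source. The trends were not fitted together and the variance includes noise of single genes, so this cannot exclude either as the main source. A stronger response to HC278 in replicate 6 as the whole source is argued against by DMSO replicate 3, which had no compound. Its deviation from DMSO replicates 1 and 2 correlated with that of HC278 replicate 6 at 0.913 across the same genes, which are not independent. The value of 0.685 given above used deviations from the group means over all tested genes. What the libraries share, such as RNA handling or the state of the cultures, stays open and was not tested.

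DNA replication and mitosis genes had a median log2 fold change of -1.03 over 66 members. Gene length and the libraries that stood apart are each argued against as the whole cause. The median was -1.05 (95% interval over members -1.17 to -1.02) with the length trend taken out, and -0.97 (-1.09 to -0.90) without both libraries. The remaining libraries still differed along the first principal component, so other variation between libraries is not excluded. Under the scaling that brought it nearest to 0 the median was -0.96 (-1.04 to -0.87). The other scalings had medians over all genes from 0.0412 to 0.124, against 0.0511 with TMM factors. They could hardly have brought these members near 0, so scaling as a cause is not decided. These intervals resample the members, which are not independent, and hold no spread between libraries. A response of the cells to HC278, such as fewer cells in cycle, is a candidate explanation that stays open, as is a difference in culture density, which the files do not record.

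The size of the rise of interferon-stimulated genes depended on HC278 replicate 6. Without it the list's median fell from 0.91 to 0.36 (95% interval -0.06 to 0.72 over members), and without any other single library it was 0.7472 or more, but the interval is too wide to say whether that library alone carries the rise. Called members went from 3 higher and 0 lower of 19 with all libraries to 8 higher and 1 lower without HC278 replicate 6. Calls over all genes went from 1672 of 15510 to 6413 of 15812, so this gain is not particular to the list and does not bear on the question. With the length trend taken out, the list's median in HC278 replicate 6 was 0.98 above that in HC278 replicates 1 and 2 (95% interval over members 0.26 to 1.13), up from 0.71 before the correction. The list as a whole still passed after it, with a median of 0.80 (95% interval over members 0.53 to 1.02, camera adjusted p = 0.00297), which argues against gene length as the whole cause. An interferon response in that culture is a candidate explanation, and IRF9 at 53.9, 51.3 and 48.9 CPM in the HC278 libraries against 22.5 to 27.2 CPM with DMSO did not follow this arrangement.

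Dividing the 6 libraries into 3 and 3 in other ways gives 10 splits with the real one, too few for a share under 0.05. The real split called 1672 genes, more than any other (1 split as large), and the highest of the others called 0. At an unadjusted p under 0.05 the real split had 4115 genes, and that of DMSO replicate 1 with HC278 replicates 1 and 2 against the rest, which puts both length-skewed libraries together, had 3666; the next had 1977. For gene lists the real split called 7 by camera, 6 of the 10 splits called as many, and the highest other called 12, that of DMSO replicates 1 and 2 with HC278 replicate 6 against the rest. Each other split still holds part of any difference between DMSO and HC278, so a list that changed with treatment can pass there too. Of the 9 others, mitosis passed in 9, DNA replication in 7, the YAP/TEAD targets in 5 and the interferon list in 6, the last with an adjusted p down to 5.59e-11 against 0.00197 in the real split. The ribosomal protein list, which did not pass in the real split (adjusted p = 0.744), passed in 7.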
